A study of Homo sapiens with 13 samples.

How the data were processed

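Cells of explanted liver and of blood were profiled with 10x Genomics 3' v3.1 chemistry, with a target of 8000 cells per lane. Per the labels' protocols, liver was digested for 30 min at 37 °C with 0.1% collagenase and 0.025% hyaluronidase before density separation, and red cells of blood were lysed for 10 min. The deposited values are raw UMI counts per gene and barcode, made by the authors with Cell Ranger on GRCh38 and, per the submitters' processing notes, read into Seurat 4.0. The Cell Ranger version and the use of strand in counting are not given in the sources used here. Each of the 13 libraries held 36601 features, and 70208 barcodes were listed in all.

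Barcodes with at least 200 detected genes and at most 20% mitochondrial UMIs were kept, 65350 in all. Doublets were scored with Scrublet as built into scanpy. Its automatic threshold called under 0.5% of cells in 9 of 13 libraries and was set aside, and the cells with the highest scores were removed instead, at 0.8% per 1000 barcodes, or 3336 cells. The 62014 cells left were scaled to 10000 UMIs, log-transformed and scaled with values limited to 10. From 2000 variable genes, 40 principal components and 15 neighbours were computed, with edges of a Jaccard overlap of at least 0.05, and Leiden clustering at resolution 1 (seed 1) gave 43 clusters of at least 30 cells. No integration across libraries was used. Clusters were named after 18 marker classes where at least 3 markers were detected in at least 20% of cells, and a name means only that a cluster is like that class. The 3 unnamed clusters held a mean of 6.62% of the cells of sAH liver libraries, 1.61% of the AC liver, 3.89% of sAH blood and 6.33% of AC blood.

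Cells are not replicates, so the UMIs of each class were summed per library where it held at least 20 cells, and libraries were the samples. The neutrophil sums held 366 to 1213 cells in sAH livers, 70 in the AC liver and 638 to 5594 in blood. Genes were tested with edgeR 4.0.16 (TMM scaling, filterByExpr, robust quasi-likelihood F tests, 2-sided, Benjamini-Hochberg adjusted p under 0.05), and mean CPM values use the TMM library sizes. A lone library is assumed to vary like the other group. Gene sets, 34 lists written by hand, were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01 where at least 5 genes were tested, and again with the correlation estimated from the data. Member genes are counted past the threshold adjusted over all tested genes, and again adjusted over the list alone. On simulated counts with the same designs, edgeR recovered 23% of 4-fold changes in blood neutrophils, 25% in neutrophils of sAH liver against blood and 99% in the comparison by CXCL8.

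The comparisons were sAH against AC in blood (n = 4 and 3), sAH liver against blood in the donors with both (n = 4 each), and sAH against AC liver neutrophils (n = 5 and 1). A further comparison set CXCL8-positive against CXCL8-negative neutrophils within each of 6 liver libraries, with the library as a block. Liver and blood were first compared without donor blocks, and the donor as a block is an alternative. For these 4 sAH donors, log2 CPM values were also taken as deviations from the mean of each tissue. Over genes, a donor's liver deviations correlated with that donor's own blood deviations at 0.339 to 0.636 in neutrophils and 0.181 to 0.438 in mononuclear phagocytes. In T cells this was -0.179 to 0.634 and in NK cells 0.037 to 0.569. Between donors the correlations were -0.503 to 0.399 over these classes, and centring on the mean of 4 donors lowers them by construction. Shares of cells were compared with exact permutation tests, 2-sided, paired where both tissues came from the same donors. A cell was CXCL8-positive with at least 1 CXCL8 UMI after thinning to 500 UMIs. Intervals for single libraries are 95% exact binomial intervals, floors for a count of 0 are set at 3 counts, and both cover counting error only.

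Genes are named by a rule fixed before the data were examined. It takes, per comparison, the 10 largest changes in each direction with an adjusted p under 0.05, a mean log2 CPM of at least 5 and fully separated groups. It adds up to 2 members per gene list and direction, and a fixed set of neutrophil genes, of which 1 is left out here, and genes named outside it are said to be so. Gene positions come from GENCODE v44, in which 36247 of 36482 gene IDs were found. Immunoglobulin, T cell receptor and haemoglobin genes are not named, and 119 genes were left out to protect the donors.

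Alternatives were RLE scaling, no low-count filter, DESeq2 1.42.0, the donor as a block, the fifth sAH liver added, no doublet removal, a limit of 10% mitochondrial UMIs, at least 500 genes, Leiden resolution 2, thinning to 1000 UMIs, at least 3 CXCL8 UMIs, no library block and leaving out each library. Counting an unnamed cytotoxic cluster as T cells and leaving out both libraries of sAH donor 3 were chosen after seeing the data. Computations used Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3.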

Results

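Single-cell RNA profiles were made from liver and blood of people with severe alcohol-associated hepatitis (sAH) or alcohol-associated cirrhosis (AC). The series asks what role neutrophils that carry interleukin-8, the neutrophil-attracting chemokine encoded by CXCL8, play in the inflammation of sAH. The 13 libraries came from 8 donors and formed 4 groups, with 5 sAH livers, 1 AC liver, 4 sAH blood samples and 3 AC blood samples. Both tissues were profiled in 4 sAH donors, numbered 2 to 5, and in AC donor 3. The libraries held 2537 to 8992 barcodes and 21818732 to 83682778 UMIs each, and 62014 cells were kept, 2282 to 7759 per library.

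Neutrophil-like cells were the largest class in each blood library but that of sAH donor 2, where mononuclear phagocyte-like cells outnumbered them (1044 against 638). The mean neutrophil-like share was 53.1 ± 19.5% of kept cells in sAH blood (SD, n = 4) and 56.5 ± 22.0% in AC blood (SD, n = 3). The difference of -3.46 percentage points was smaller than the spread between donors (exact two-sided permutation p = 0.771, adjusted p = 0.964 over 5 classes), and its direction turned without the blood library of sAH donor 2 (5.57 points), AC donor 1 (5.39) or AC donor 3 (0.0095). In the 4 sAH donors with both tissues, neutrophil-like cells made up 22.6 ± 13.8% of liver cells, and the share was lower in liver than in blood in 4 of 4 pairs. That difference of -30.5 points gave an exact paired permutation p of 0.125, the smallest that 4 pairs allow (adjusted p = 0.312). T cell-like cells made up 24.2 ± 10.6% of those livers and 10.9 ± 8.80% of the blood samples (exact paired permutation p = 0.25, adjusted p = 0.417). Liver was digested and density-separated and blood was not, so effects of preparation on these shares cannot be told apart from tissue. The single AC liver had another makeup, with 35.1% cholangiocyte-like cells (95% exact binomial interval 34.0 to 36.3) against 2.35 ± 1.31% in the sAH livers (SD, n = 5). Neutrophil-like cells were 0.999% of that liver (70 cells, interval 0.779 to 1.26), T cell-like cells 0.870% (61 cells, interval 0.666 to 1.12; 138 cells without doublet removal), and the intervals cover counting error only.

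To measure how common CXCL8 expression was among neutrophils, each cell was thinned to 500 UMIs, which left no cell out. CXCL8 (chromosome 4, 73740519 to 73743716, GRCh38) was detected in 65.4 ± 17.9% of neutrophil-like cells of sAH livers (SD, n = 5), with a range of 44.5 to 89.9%. In sAH blood the share was 2.22 ± 1.24% (SD, n = 4). The share was higher in liver than in blood in 4 of 4 donors, by 57.0 percentage points on average (exact paired permutation p = 0.125, the smallest that 4 pairs allow). AC blood neutrophils held CXCL8 in 5.65 ± 1.71% of cells (SD, n = 3), and each of the 4 sAH blood libraries lay below every AC blood library. The difference of -3.43 points gave an exact two-sided permutation p of 0.0571, where the smallest possible is 0.0286. In the AC liver, 21 of 70 neutrophil-like cells held CXCL8, or 30.0% (95% exact binomial interval 19.6 to 42.1), below each of the 5 sAH livers. Of these 70 cells, 41 lay in cluster 7, 14 in cluster 3, which was 97.7% AC blood cells, and 12 in the shallow cluster 40. Clusters 7 and 17 held 66.1% and 29.3% of sAH liver neutrophils. Shares within a cluster were not compared, so the makeup of the AC cells cannot be told apart from a lower share. At Leiden resolution 2, with 58 AC liver neutrophils, the share was 34.5% in the AC liver and 58.4 ± 29.0% in the sAH livers, of which those of donors 2 and 4 lay below it. The neutrophil-like cells of the liver of donor 2 fell there from 512 to 24 with and 59 without CXCL8. Those of donor 4 fell from 366 to 22 and 57. Without thinning, the shares were 79.1% in sAH liver, 44.3% in AC liver, 6.66% in sAH blood and 13.9% in AC blood.

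T cells, which should lack CXCL8, gave the background of free RNA measured the same way. At 500 UMIs, 0.805% of T cell-like cells of sAH livers held a CXCL8 UMI, at most 2.40% in any of the 5. None did among the 61 T cell-like cells of the AC liver, which allows up to 4.92%, or in any sAH blood library, which allows up to 0.342 to 2.5% per library, and 0.06% did in AC blood. Median depth was 896 to 4662 UMIs in sAH liver neutrophils, 1740 in AC liver, 1340 to 5785 in sAH blood and 2008 to 4369 in AC blood. T cells were deeper, with medians of 5216 to 11559 UMIs in sAH liver, 5757 in AC liver, 10996.5 to 22440 in sAH blood and 8691 to 12029 in AC blood, and 10.4% of sAH liver T cells held CXCL8 before thinning. Of all CXCL8 UMIs in a library, neutrophil-like cells held 68.9 ± 25.1% in the sAH livers (SD, n = 5) and 6.46% in the AC liver. There, mononuclear phagocyte-like cells held 61.0% and cholangiocyte-like cells 30.4%. In the liver of sAH donor 4, phagocyte-like cells also held more than neutrophil-like cells, 66.2% against 28.6%. Mononuclear phagocyte-like cells carried CXCL8 in 7.36% of cells in sAH liver, 3.73% in AC liver, 0.268% in sAH blood and 0.0757% in AC blood at 500 UMIs. Their summed CXCL8 level ran the other way between the livers, at 340.7 CPM in the AC liver and 200.5 ± 152 CPM in the sAH livers (SD, n = 5).

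**Figure D1:**
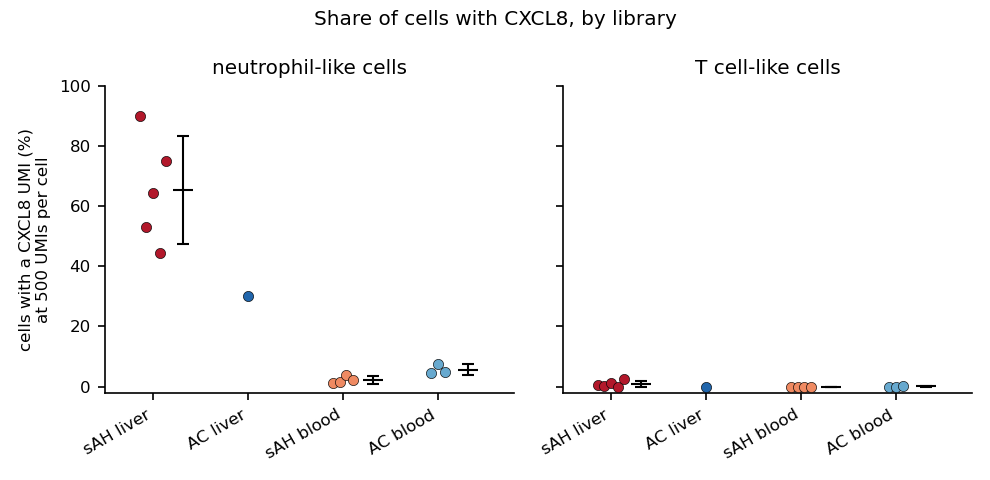
Percent of neutrophil-like and T cell-like cells with a CXCL8 UMI after thinning to 500 UMIs, 1 dot per library, with the mean and SD as bars. The 5 sAH livers lie between 44.5 and 89.9% and the 7 blood libraries at 7.62% or less.

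Blood neutrophils of sAH and AC donors were compared to ask how the circulating cells of the 2 diseases differ. A group of neighbouring genes on chromosome 15 was nearly silent in sAH and expressed in AC. SLC12A1, which encodes a sodium-potassium-chloride cotransporter best known from the kidney, fell from 199 ± 118 CPM in AC (SD, n = 3) to 1.25 ± 0.76 CPM in sAH (SD, n = 4). Its log2 fold change was -7.16 ± 0.65 (SE; edgeR adjusted p = 0.00557). MYEF2, named as a repressor of myelin basic protein expression, fell by 7.42 on the log2 scale (adjusted p = 0.00816), from 14.8 to 0.09 CPM. The other 3 genes that passed, all lower in sAH, were the long noncoding AC066612.2 (-6.88), AC066612.1 (-7.05) and AC023355.1 (-5.21).

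These 5 calls of 10514 genes tested, all chosen for mention after their values were seen, lay within 197 kb (48134632 to 48331856), a span with 6 tested genes. No gene rose, 984 had an unadjusted p under 0.05, and DESeq2 called 72. AC066612.1 and AC066612.2 lie antisense within SLC12A1, and the use of strand in counting is not given in the sources used here, so their reads cannot be parted from those of SLC12A1. Without the blood library of sAH donor 2 the count was 2, and SLC12A1, MYEF2 and AC023355.1 each had an adjusted p of 0.0510. The call of AC023355.1 also ended without the blood library of AC donor 2 (adjusted p = 0.0581) or sAH donor 4 (0.0790). With every sum thinned to 918922 UMIs, the smallest, the count was 1, SLC12A1 (-7.38 ± 0.68), and it ran from 1 to 4 over 10 random draws, added after the result was seen. In the first draw AC066612.2 (-7.81 ± 0.89, against an SE of 0.56 unthinned) and AC023355.1 (-5.54 ± 0.79, against 0.53) had larger errors and an adjusted p of 0.130, and MYEF2 and AC066612.1 had too few counts to be tested. SLC12A1 is the leading gene of neutrophil cluster 2, which held 27.3% of sAH and 16.3% of AC blood neutrophils. Cluster 3, to 86.7% from 1 AC blood library, held 37.3% of AC and 0.768% of sAH blood neutrophils. Cluster 0 held 36.8% of those of sAH and 30.7% of those of AC. These shares pool cells over libraries, and the blood library of sAH donor 5 gave 5594 of the 9631 sAH cells. Of the tested genes, 12.2% separated the groups fully, where chance gives 5.71%.

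**Figure D2:**
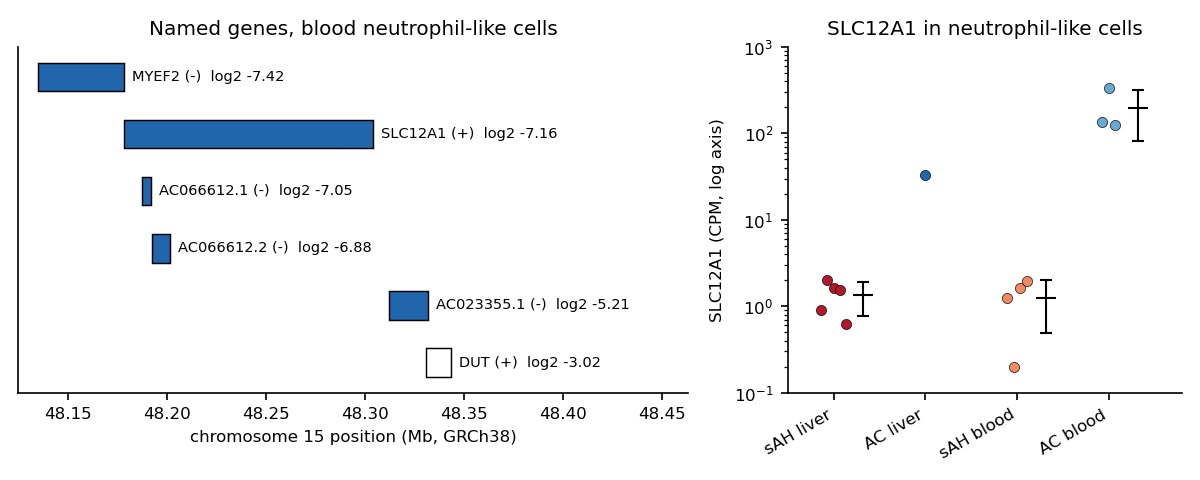
Position on chromosome 15 of the 5 genes that fell in sAH blood neutrophils (filled) and of DUT, which did not pass (open), with log2 fold changes (left). On the right, CPM of SLC12A1 in neutrophil-like cells on a log axis, 1 dot per library, with group means and SD.

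At the end of that span, DUT, an enzyme that keeps uracil out of DNA, had a log2 fold change of -3.02 ± 0.45 that did not pass (adjusted p = 0.141), and it overlaps AC023355.1 on the other strand. CCL4, a chemokine that attracts monocytes and T cells, was at 34.7 CPM in AC and 5.45 CPM in sAH (log2 fold change -2.59 ± 0.40, adjusted p = 0.145). DESeq2 and the fit without a low-count filter called both DUT and CCL4, which were chosen for mention after their values were seen. CXCL8 was at 146 ± 16.1 CPM in AC and 65.9 ± 42.9 CPM in sAH (log2 fold change -1.13 ± 0.42, adjusted p = 0.529). CXCR2, the receptor for interleukin-8, had a log2 fold change of -1.27, the homing receptor CXCR4 of -1.29, the chemokine CCL3 of -1.44, the alarmin S100A8 of -1.14 and the IgG receptor FCGR3B of -1.25. Without the blood library of sAH donor 5, CXCR2 was at -2.21, S100A8 at -2.95 and FCGR3B at -2.02. S100A8 was at -0.36 without AC donor 1 and at -0.73 without sAH donor 2, and FCGR3B at -0.58 without AC donor 3. None of these genes passed, nor did 4 other genes fixed for this class, whose log2 fold changes ran from -1.15 to -0.20 with adjusted p of 0.580 or more.

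Several gene lists were called in blood neutrophils with the preset correlation only, and no member passed alone over all genes. The 30 genes of oxidative phosphorylation, the nuclear-encoded machinery of mitochondrial respiration, had a median log2 fold change of -0.85 in sAH, and camera called the list lower (adjusted p = 1.03e-08). The 30 ribosomal protein genes had a median of -0.73 (adjusted p = 4.15e-08). Chemokines and cytokines were lower too (adjusted p = 9.30e-05, 17 genes), and 3 of them fell when adjusted over the list alone. The 16 genes of class I antigen presentation (adjusted p = 7.45e-04) and the 47 interferon-stimulated genes (adjusted p = 0.00330) were called lower as well. None of these calls held with an estimated correlation, where the first 4 lists had an adjusted p = 0.551 with an estimated correlation and the last 0.697. The 13 mitochondrially encoded genes, a sign of RNA quality, moved the other way with a median of 0.59 (adjusted p = 0.0284; adjusted p = 0.677 with an estimated correlation). In all, camera called 13 of 28 lists in this class with the preset correlation and 0 with the estimated one.

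In blood mononuclear phagocyte-like cells, which may include dendritic cells, no single gene was called between the diseases by edgeR. HLA-DRA, which presents antigen to helper T cells, was at 1163 CPM in AC and 913 CPM in sAH (log2 fold change -0.35 ± 0.29, adjusted p = 0.854), and S100A8 had a log2 fold change of -0.56. SLC12A1, named after its values were seen, was at 3.74 CPM in AC and 0.22 CPM in sAH (log2 fold change -4.19 ± 0.72, adjusted p = 0.850) and was called by DESeq2. A further 10 fixed genes had log2 fold changes of -1.62 to 1.14. Class II antigen presentation genes had a median of -0.39 over 15 genes and were called lower as a list (adjusted p = 3.24e-05; adjusted p = 0.660 with an estimated correlation). The mitochondrially encoded genes were called higher, with a median of 0.60 (adjusted p = 1.1e-06). Ribosomal protein genes (adjusted p = 2.6e-06) and transcripts of neutrophils (adjusted p = 1.1e-06) were called lower. Each of these 3 had an adjusted p = 0.660 with an estimated correlation. edgeR called 0 of 15544 genes, with 767 at an unadjusted p under 0.05 and 21 called by DESeq2, and 7.1% separated the groups fully, where chance gives 5.71%. Without the blood library of AC donor 3 or sAH donor 3, HLA-DRA was at -0.18 and -0.15, and without that of AC donor 1 or sAH donor 3, S100A8 was at -0.34 and -0.35. Cluster 1 held 86.9% of the class in AC and 68.5% in sAH, where cluster 28, to 92.9% from 1 library, held 14.9%.

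Blood T cells of the 2 diseases also had no gene past the threshold (edgeR, 0 of 13871 genes), with 517 at an unadjusted p under 0.05 and 0 called by DESeq2. Cytotoxic effector genes, such as granzymes and perforin, had a median log2 fold change of -0.59 over 21 genes and were called lower in sAH (adjusted p = 3.06e-04; adjusted p = 0.742 with an estimated correlation). That call ended when an unnamed cytotoxic cluster, left out because its leading genes favoured NK cells, was counted as T cells (adjusted p = 0.923). Genes of mucosal-associated and gamma-delta T cells had a median of -0.45 over 11 genes (adjusted p = 0.00251; adjusted p = 0.375 with an estimated correlation). The mitochondrially encoded genes were called higher in sAH here as well (median 0.64, adjusted p = 3.24e-06; adjusted p = 0.742 with an estimated correlation). Neutrophil transcripts were called lower (adjusted p = 5.44e-05; adjusted p = 0.742 with an estimated correlation).

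Liver and blood neutrophils of the same 4 sAH donors were compared to ask how the cells differ once in the diseased organ. CXCL8 rose from 62.7 ± 40.9 CPM in blood to 5314 ± 3292 CPM in liver (SD, n = 4 each; log2 fold change 6.40 ± 0.61 SE, edgeR adjusted p = 4.85e-04). CD83, a surface protein of activated antigen-presenting cells, rose from 8.05 to 602 CPM (log2 fold change 6.22 ± 0.47), and the early-response nuclear receptor NR4A3 rose by 7.30 ± 0.66. PLAUR, the urokinase receptor, rose from 203 to 2016 CPM (3.31 ± 0.40). CCL3, a chemokine for monocytes and T cells, rose by 5.11 ± 0.91 and CXCR4 by 2.92 ± 0.63, a call that ended without the blood library of donor 4 (2.83, adjusted p = 0.0709). Among the genes that fell, the lysosomal lipase-like PLBD1 had a log2 fold change of -2.07, FAM160B1 of -1.95, the phosphatase subunit PPP2R5A of -1.90, the cell cycle repressor RBL2 of -1.81 and the iron-regulatory protein IREB2 of -1.77. In total, 524 of 9379 genes rose and 206 fell.

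Most immediate-early and dissociation-linked genes rose in liver neutrophils, 22 of 26 (23 adjusted over the list alone), and camera called the list higher (adjusted p = 4.95e-26; 0.0238 with an estimated correlation). Of 26 NF-kB targets, 16 rose (21 adjusted over the list alone), among them TNFAIP3, which restrains NF-kB signalling (3.83 ± 0.57). The list kept its call with an estimated correlation (adjusted p = 4.75e-20 and 0.0401). Of 18 hypoxia-response genes, 9 rose and 12 rose with 1 falling when adjusted over the list alone. Examples are the angiogenic factor VEGFA (4.46 ± 0.45), the stress-induced mTOR inhibitor DDIT4 (4.51 ± 0.47) and the collagen-modifying P4HA1 (3.92 ± 0.47), and the list was called with both correlations (adjusted p = 2.13e-11 and 0.0238). Glycolysis had 10 of 18 genes higher and 1 lower (the same adjusted over the list alone), with PKM at 1.99 and PFKFB3 at 1.48, and its call was lost in the second test (adjusted p = 3.83e-05; adjusted p = 0.113 with an estimated correlation). Glucocorticoid-responsive genes rose in 6 of 20 (6 adjusted over the list alone; adjusted p = 4.57e-05, and 0.0238 with an estimated correlation). The survival genes BCL2 (3.24) and BCL2A1 (2.01) rose. So did G0S2, an inhibitor of fat breakdown (4.47 ± 0.85), HMOX1, which degrades haem (3.55), PHACTR1 (3.98) and the deubiquitinase JOSD1 (3.62).

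Chemokines and cytokines rose in 8 of 17 genes in liver neutrophils, and adjusted over the list alone 9 rose and 1 fell (adjusted p = 4.00e-10; adjusted p = 0.0778 with an estimated correlation). IL1B, the gene of interleukin-1 beta, had a log2 fold change of 2.97 ± 1.21 that did not pass (adjusted p = 0.160), and of 1.51 without the liver library of donor 3. Class II antigen presentation genes rose in 5 of 11 (8 adjusted over the list alone; adjusted p = 9.16e-05; adjusted p = 0.195 with an estimated correlation), including HLA-DQA1 (3.65). HLA-DRA rose by 2.03 ± 0.54 (adjusted p = 0.0443), but passed in only 1 of the 8 fits that left out a library. Its log2 fold change was 1.77, 1.73 and 1.99 without the blood libraries of donors 3, 4 and 5, and 2.19, 1.97, 1.93 and 1.95 without the liver libraries of donors 2, 3, 4 and 5. C1QA, C1QB and C1QC in these neutrophil sums were at 0.532 to 7.94% of their level in phagocytes of the same liver. HLA-DRA was at 49.09 to 102.34 CPM in the liver neutrophils. Phagocyte RNA could thus bring part of the class II RNA, and how much was not tested. Heat shock genes rose in 6 of 14 (9 adjusted over the list alone; adjusted p = 1.19e-04; adjusted p = 0.453 with an estimated correlation). The chaperone DNAJB1 (5.83 ± 1.43, adjusted p = 0.0369) lost its call with donors as blocks (3.71, adjusted p = 0.215), without any of the 4 blood libraries (5.59, 5.94, 5.75 and 6.00 without donors 2, 3, 4 and 5) and without the liver library of donor 5 (3.03). CXCR2 and S100A8 did not pass, at -0.74 and -1.30, and both turned positive without the blood library of donor 5, at 0.19 and 0.49, while without the liver library of donor 5 they were at -1.62 and -2.30. A further 3 fixed genes did not pass (-1.75 to -0.40, adjusted p of 0.418 or more). Alarmin genes gave no call (adjusted p = 0.993), with a median of -0.75, a mean of -0.27 and a test direction of higher.

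The liver neutrophil sums also held RNA of other cells and more mitochondrially encoded RNA. Hepatocyte transcripts rose in 3 of 6 genes tested (3 adjusted over the list alone; adjusted p = 1.54e-05; adjusted p = 0.0587 with an estimated correlation), and mitochondrially encoded genes in 4 of 13 (11 adjusted over the list alone; adjusted p = 2.31e-06; adjusted p = 0.335 with an estimated correlation). Monocyte transcripts rose in 5 of 12 and fell in 1 (6 and 1 adjusted over the list alone; adjusted p = 0.00139; adjusted p = 0.229 with an estimated correlation). Clusters 7 (56.8%) and 17 (37.4%) held the neutrophils of these 4 livers, clusters 0 (36.8%), 2 (27.3%), 6 (16.1%) and 16 (13.7%) those of sAH blood. Clusters 17 and 16 were named neutrophil-like on low scores, the mean standardised level of the class markers. These were 0.72 and 0.473, against 1.43 in cluster 7 and 1.146 to 1.634 in clusters 0, 2 and 6. CXCL8, G0S2, PLAUR and PHACTR1 are among the 10 leading genes of cluster 7. With donors as blocks, 1082 genes rose and 868 fell. The count of 730 came to 355 without the blood library of donor 4, and to 431, 465 and 401 without the liver libraries of donors 2, 3 and 5. It was 647 without both libraries of donor 3, which stood apart as clusters 16 and 17, an alternative chosen after seeing the data. At Leiden resolution 2, the neutrophil-like cells of the liver of donor 2 fell from 512 to 24 with and 59 without CXCL8. Those of donor 4 fell from 366 to 22 and 57. An unnamed cluster of 1065 cells at that resolution, 98.3% from sAH liver, had neutrophil as its best class. It had a median of 1234 UMIs and no class marker among its leading genes. With these cell names, 241 genes passed, and P4HA1, G0S2, CXCR4, BCL2, DNAJB1 and IREB2 no longer did. Without the low-count filter, G0S2 (adjusted p = 0.0744), CXCR4 (adjusted p = 0.103) and DNAJB1 (adjusted p = 0.128) did not pass either. Of the tested genes, 16.9% separated the tissues fully, where chance gives 2.86%.

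**Figure D3:**
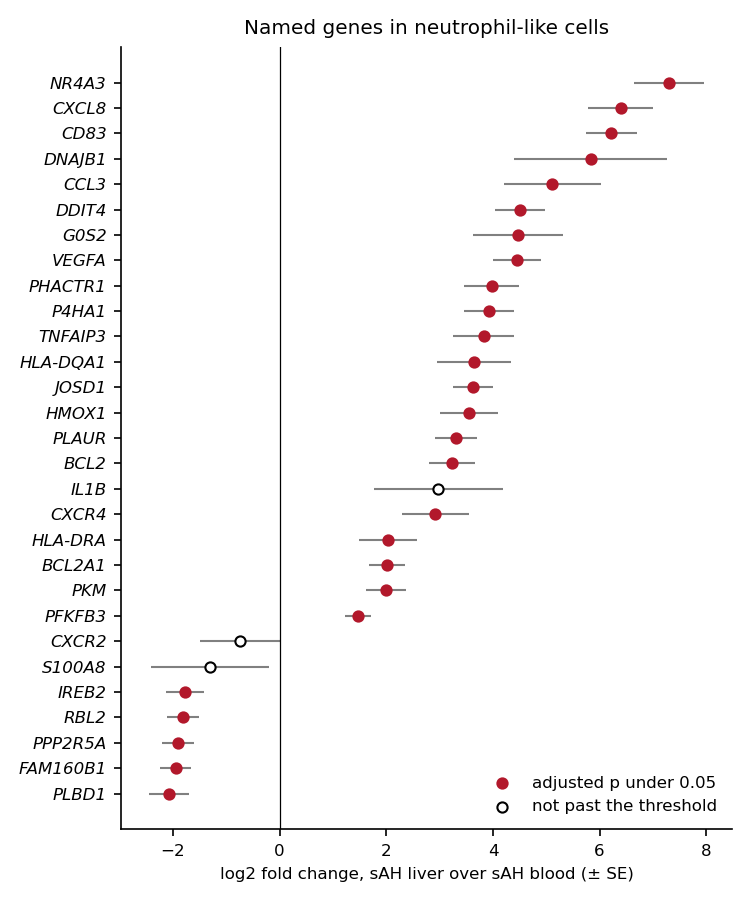
Log2 fold change (± SE) of the named genes in neutrophil-like cells of liver over blood of the same 4 sAH donors. Filled dots passed an adjusted p of 0.05 in edgeR, and open dots did not.

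Mononuclear phagocytes, mainly the monocytes of blood and the monocytes and macrophages of liver, differed between the tissues of the 4 sAH donors in genes of macrophages, chemokines and stress. The class may also hold conventional dendritic cells, after which no cluster was named. In cluster 10 they were the second-best class (score 1.325 against 1.625). At Leiden resolution 2, a cluster of 196 cells took that name, 46.4% of them from sAH liver and 13.8% from sAH blood. RGS1, which dampens chemokine receptor signalling, rose from 1.5 to 632 CPM (log2 fold change 8.88 ± 1.04), and FRMD4A rose by 7.24 ± 0.80. CXCL8 rose from 3.24 ± 1.61 to 140.5 ± 68.4 CPM (SD, n = 4 each; 5.41 ± 0.56, edgeR adjusted p = 0.00104), and remained far below its level in liver neutrophils. The immediate-early factor JUN rose by 5.99 ± 0.34, the repressor ZNF331 by 5.75, and oncostatin M, OSM, by 5.13 ± 0.34. The small heat shock protein HSPB1 rose by 4.96, CD83 by 4.82 and the endocytic adaptor DAB2 by 4.21. Among the genes that fell, with a mean log2 CPM of at least 5 and fully separated groups, were MPP7 (-2.50), LIN7A (-2.03), MEGF9 (-1.94), the transcription factor KLF13 (-1.85) and MGST1, a membrane glutathione transferase (-1.84 ± 0.22). In total, 1893 of 15875 genes rose and 1055 fell.

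Genes of scar-associated macrophages, a population described in cirrhotic liver, rose in 15 of 17 (15 adjusted over the list alone), with the fatty acid-binding protein FABP5 at 3.88. The list was called with both correlations (adjusted p = 2.13e-37 and 0.00512). Chemokines and cytokines rose in 17 of 23, and adjusted over the list alone 18 rose and 1 fell (adjusted p = 7.90e-19; 0.0179 with an estimated correlation), including CCL3 (5.09) and CXCL2 (4.46). IL1B rose by 1.92 ± 0.46 (adjusted p = 0.0224), a call that ended without the blood libraries of donors 2 (1.88) and 4 (1.71), without the liver library of donor 5 (1.91) and without the low-count filter (1.90). Markers of Kupffer cells, the resident macrophages of liver, rose in 8 of 15 (9 adjusted over the list alone; adjusted p = 1.67e-08; adjusted p = 0.0579 with an estimated correlation). Among them were the folate receptor FOLR2 (3.45) and the iron exporter SLC40A1 (2.66). Class II antigen presentation genes rose in 11 of 15, with 1 falling when adjusted over the list alone (adjusted p = 6.15e-10; adjusted p = 0.163 with an estimated correlation), including HLA-DRA (1.64) and CD74 (1.58). Hypoxia-response genes rose in 12 of 20 (14 adjusted over the list alone; adjusted p = 2.50e-10; adjusted p = 0.0579 with an estimated correlation), including VEGFA (3.40) and the lipid droplet protein PLIN2 (2.72).

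Immediate-early genes rose in 20 of 26 (23 adjusted over the list alone; adjusted p = 1.98e-22; adjusted p = 0.0579 with an estimated correlation) in liver phagocytes, FOSB by 4.14. Heat shock genes rose in 16 of 18 (18 adjusted over the list alone; adjusted p = 3.64e-14; adjusted p = 0.181 with an estimated correlation). NF-kB targets rose in 12 of 26, with 13 higher and 1 lower adjusted over the list alone (adjusted p = 7.77e-05; adjusted p = 0.165 with an estimated correlation). Genes of the NADPH oxidase and extracellular traps fell in 3 of 13, NCF1 by 1.76 on the log2 scale, and adjusted over the list alone 1 rose and 4 fell (adjusted p = 0.0221; adjusted p = 0.429 with an estimated correlation). The alarmins S100A8 (-1.43, adjusted p = 0.0971) and S100A12 (-1.80, adjusted p = 0.0794) did not pass. Both passed with donors as blocks (-1.66 and -2.04), with DESeq2 (-1.46 and -1.83) and without the liver library of donor 4 (-2.14 and -2.58). S100A12 also passed without the blood library of donor 3 (-2.08). A further 3 fixed genes did not pass (-1.28 to -0.83, adjusted p of 0.110 or more). Hepatocyte transcripts rose in 6 of 11 genes here too (7 adjusted over the list alone; adjusted p = 3.12e-05; adjusted p = 0.146 with an estimated correlation). The list of T and NK cell transcripts (adjusted p = 0.0185; adjusted p = 0.563 with an estimated correlation) lost its call with donors as blocks (adjusted p = 0.104), and that of neutrophil transcripts gained one (from 0.134 to 0.0231). Clusters 10 (32.7%), 12 (30.3%) and 5 (27.8%) held the class in these 4 livers and clusters 1 (68.5%) and 28 (14.9%) in sAH blood. The count of 2948 came to 1827 and 1804 without the blood libraries of donors 2 and 5, and to 1726 and 1690 without the liver libraries of donors 3 and 5. DESeq2 called 4675.

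T cells of sAH livers had more RNA of tissue-residency genes and less of many naive-cell genes than blood T cells of the same 4 donors. ITGA1, an integrin that binds collagen, rose from 4.23 ± 2.82 to 141 ± 22.4 CPM (SD, n = 4 each; log2 fold change 5.05 ± 0.44, edgeR adjusted p = 9.53e-05). The liver-homing receptor CXCR6 rose by 4.44 ± 0.33, ITGAE, which binds E-cadherin, by 2.36, and RGS1 by 4.64. TSHZ2 fell from 752 to 32.1 CPM (-4.55 ± 0.29), LEF1, a transcription factor of naive T cells, had a log2 fold change of -3.60, and the lymph node-homing receptor CCR7 of -3.36. EDA (-4.14), FHIT (-3.26) and the growth factor receptor IGF1R (-2.73) fell as well. In total, 1373 of 13431 genes rose and 1067 fell.

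All 15 tissue-residency genes rose in liver T cells (15 adjusted over the list alone), and the call held with both correlations (adjusted p = 3.04e-26 and 0.0129). Of 15 genes of naive and central memory cells, 10 fell (10 adjusted over the list alone; adjusted p = 1.30e-12, and 0.0393 with an estimated correlation). Cytotoxic effectors rose in 15 of 22 (16 adjusted over the list alone; adjusted p = 5.95e-23 and 0.0218), among them GZMA (3.51) and the death ligand FASLG (5.25). Genes of T cell activation and exhaustion rose in 15 of 18 (15 adjusted over the list alone; adjusted p = 3.34e-15 and 0.0196), including the inhibitory receptor LAG3 (2.90). Chemokines and cytokines rose in 9 of 12 (10 adjusted over the list alone; adjusted p = 1.04e-13 and 0.0218), with CCL4 at 6.10 ± 0.63 and CCL5 at 3.41. Genes of mucosal-associated and gamma-delta T cells rose in 8 of 11 (11 adjusted over the list alone; adjusted p = 4.79e-10 and 0.0361), including the ion transporter SLC4A10 (3.42) and IL23R (4.45). Class II genes rose in 7 of 11 (8 adjusted over the list alone; adjusted p = 2.06e-06 and 0.0393), HLA-DRB1 by 1.88, and AREG, a repair-linked growth factor, rose by 3.64.

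Immediate-early genes rose in 19 of 23 and fell in 1 in liver T cells (20 and 1 adjusted over the list alone; adjusted p = 9.52e-25, and 0.0393 with an estimated correlation), with FOS at 5.85 ± 0.52, JUN at 5.19 and DUSP1 at 5.17. Heat shock genes rose in 13 of 18 (15 adjusted over the list alone; adjusted p = 7.95e-08; adjusted p = 0.288 with an estimated correlation). HSPA1A rose by 6.50 ± 1.13, and its reads may be split with its near-identical copy HSPA1B. Hepatocyte transcripts rose in 5 of 6 genes (5 adjusted over the list alone; adjusted p = 1.01e-05; adjusted p = 0.183 with an estimated correlation). The list of monocyte suppression in systemic inflammation passed only with donors as blocks (adjusted p = 0.104 without and 0.0438 with them). When the unnamed cytotoxic cluster was counted as T cells, a choice made after seeing the data, 1436 genes passed in place of 2440. The calls of GZMA (0.87), CCL5 (0.76), FASLG (1.93), LAG3 (1.17) and HLA-DRB1 (0.65) then ended, and the cytotoxic list passed in 3 of 22 genes (adjusted p = 0.0381; adjusted p = 0.690 with an estimated correlation). Tissue residency then rose in 12 of 15 genes (0.0117 with an estimated correlation), activation in 7 of 18 (0.0436) and naive genes fell in 8 of 15 (0.0804). Cluster 4 held 81.8% of blood T cells and has LEF1, CCR7 and EDA among its 10 leading genes. T cells of these 4 livers lay in clusters 13 (35.6%), 9 (31.4%, with SLC4A10 among its leading genes) and 19 (22.0%).

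**Figure D4:**
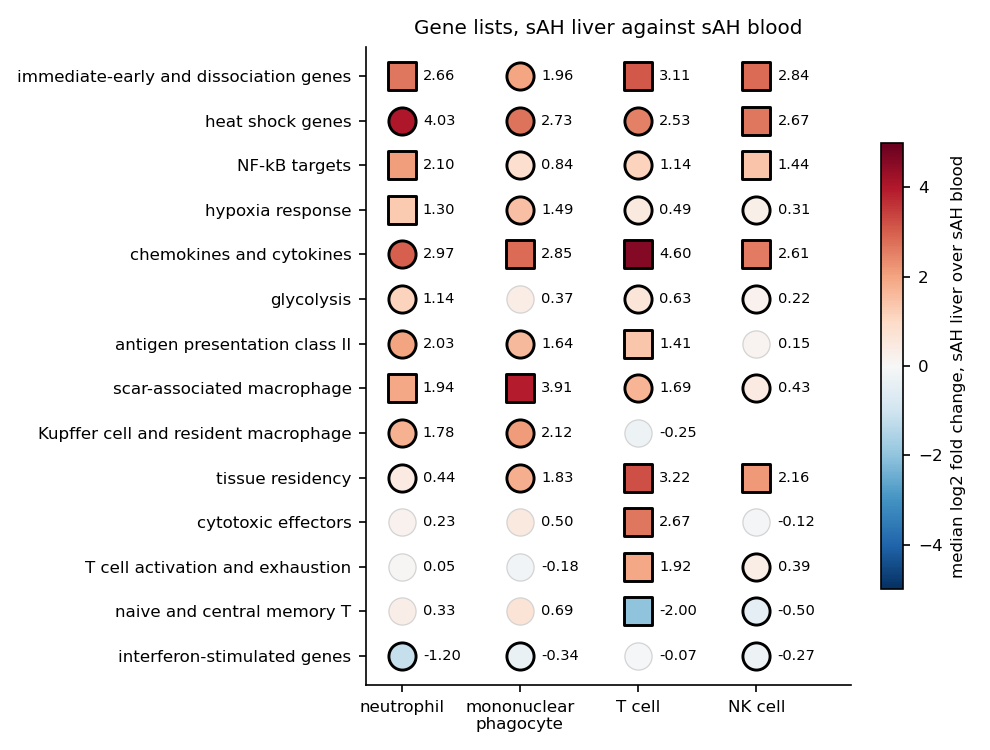
Median log2 fold change of gene lists (number and colour) in liver over blood of 4 sAH donors, for 4 cell classes. Squares mark lists called by camera with the preset and the estimated correlation, thick-edged circles those called with the preset correlation only, and grey edges lists not called.

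The neutrophils of the 5 sAH livers were set against those of the single AC liver, which gave 70 cells and 138294 UMIs, so the AC value has no replicate. CXCL8 was at 3144 CPM in the AC liver and 7089 ± 5061 CPM in the sAH livers (SD, n = 5), a log2 fold change of 1.17 ± 0.94 that did not pass (edgeR adjusted p = 0.638). CXCR4 had a log2 fold change of 1.34 and IL1B of 3.70 ± 2.47, while S100A8 was at -1.30 and FCGR3B at -1.33. Without the liver library of sAH donor 1, CXCL8 was at 0.63, CXCR4 at 0.81 and S100A8 at -2.31. SLC12A1, named after its values were seen, was at 32.8 CPM in the AC liver and 1.34 ± 0.57 CPM in the sAH livers (-4.69 ± 1.17). The AC value comes from the sum of 138294 UMIs. It adds no further donor, since the blood of AC donor 3 was already among the AC blood libraries. A further 7 fixed genes had adjusted p of 0.627 or more. edgeR called 0 of 7897 genes, with 747 at an unadjusted p under 0.05 and 4 called by DESeq2, and on simulated counts of this design it recovered 0% of 4-fold changes. The list calls that follow are against this 1 library, and none held with an estimated correlation. Immature neutrophil-like cells, with granule protein genes among their leading genes, were a class of their own and were not in these neutrophil sums. NF-kB targets were called higher as a list (26 genes, 0 past over all genes and 5 up adjusted over the list alone; adjusted p = 1.16e-05; adjusted p = 0.586 with an estimated correlation). Hypoxia-response genes were called higher (19 genes, 0 past and 5 up adjusted over the list alone; adjusted p = 0.00817; adjusted p = 0.586 with an estimated correlation). Granule proteins of immature neutrophils were called lower (8 genes, 0 past and 2 down adjusted over the list alone; adjusted p = 1.16e-05; adjusted p = 0.400 with an estimated correlation). Hepatocyte transcripts were called lower as a list against that 1 library (20 genes, median -2.69), with 0 past and 3 down adjusted over the list alone (adjusted p = 3.47e-14; adjusted p = 0.586 with an estimated correlation). The list of monocyte suppression was called lower (median -0.62, mean 0.26; adjusted p = 0.0490; adjusted p = 0.586 with an estimated correlation). Cluster 7 held 58.6% of the AC liver neutrophils, cluster 3 held 20.0% and cluster 40 held 17.1%, against clusters 7 and 17 in sAH liver.

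The difference between tissues was also compared between the diseases over all 4 groups of neutrophils. Of 13392 genes, 0 passed this interaction test in edgeR, with 1036 at an unadjusted p under 0.05, and it was fitted with edgeR alone. For CXCL8, the log2 difference between sAH and AC was larger in liver than in blood by 2.68 ± 1.14 (SE; edgeR adjusted p = 0.594). The test rests on 1 AC liver and was fitted without donor blocks, although some donors gave both tissues.

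Liver neutrophils with and without CXCL8 were compared within each of the 6 liver libraries, to describe the CXCL8-positive cells that the series is about. Each cell was assigned after thinning to 500 UMIs, so a cell without CXCL8 had none detected at that depth. CXCR4 was higher in the positive cells (log2 fold change 1.19 ± 0.14, adjusted p = 4.45e-10 in edgeR; 1341 against 602 CPM), as were the chemokine CCL3L1 (1.20 ± 0.19) and IER3, an early-response survival gene (0.98). NFKBIA, the inhibitor of NF-kB, was higher by 0.90, TNFAIP3 by 0.68, G0S2 by 0.72 and PHACTR1 by 0.78, and so were HPCAL1 and KATNBL1, both by 0.69. IL1B was higher by 0.82 ± 0.22 (adjusted p = 0.0103), but not at 1000 UMIs (0.88, adjusted p = 0.0800), and it left the tested genes when the liver library of donor 1, 3 or 5 was left out. The alarmins S100A12 (-1.25 ± 0.17) and S100A8 (-0.76 ± 0.10, adjusted p = 5.23e-08) were lower, as were MPP7 (-1.12), the nuclear envelope protein SYNE1 (-1.11), the antiviral ZC3HAV1 (-1.02) and PYGL, which breaks down glycogen (-0.80). CCL3L1 was higher by 2.05 without the liver library of donor 3. CCL3L1 and IL1B are among the leading genes of cluster 17, G0S2 and PHACTR1 among those of cluster 7, and reads of CCL3L1 may be split with its near-identical copies.

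A further 4 fixed genes, CXCR1, CXCR2, FCGR3B and HLA-DRA, did not pass (-0.04 to 0.18, adjusted p of 0.838 or more). In total, 52 of 1933 genes were higher and 45 lower in CXCL8-positive neutrophils with the library as a block, and 9.7% separated the 2 sums in every library, where chance gives 3.12%. NF-kB targets were higher in 5 of 19 (6 adjusted over the list alone; adjusted p = 1.23e-06; adjusted p = 0.147 with an estimated correlation). Hypoxia-response genes were higher in 4 of 12 (4 adjusted over the list alone; adjusted p = 4.03e-05; adjusted p = 0.147 with an estimated correlation). Chemokines and cytokines other than CXCL8 were higher in 5 of 9 (5 adjusted over the list alone; adjusted p = 4.33e-05; adjusted p = 0.0972 with an estimated correlation). Glycolysis genes were higher in 2 of 9 (5 adjusted over the list alone; adjusted p = 9.03e-04; adjusted p = 0.147 with an estimated correlation). Calgranulins and alarmins were lower in 3 of 10 (4 adjusted over the list alone; adjusted p = 1.16e-05; adjusted p = 0.0889 with an estimated correlation). The list of monocyte suppression was called lower (median 0.11, mean -0.12; adjusted p = 0.0225; adjusted p = 0.227 with an estimated correlation). Without the library block 0 genes passed. The count was 52 without the liver library of donor 2. It was 24 without the low-count filter, where S100A8 (adjusted p = 0.139), MPP7, SYNE1, ZC3HAV1 and PYGL did not pass. At Leiden resolution 2 it was 2, with only 24 and 22 CXCL8-positive cells in the livers of donors 2 and 4. IER3, NFKBIA, PHACTR1, G0S2, TNFAIP3, HPCAL1, KATNBL1, S100A8 and PYGL then no longer passed, with log2 fold changes in the same direction.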

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

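The tests of RNA from other cells, of overlapping genes, of free RNA and of digestion, and the counts over other splits of the samples, were chosen only after the result was seen. Those of sample structure, depth and macrophage RNA were chosen before.

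Genes around SLC12A1 on chromosome 15 were lower in sAH than in AC blood neutrophils. RNA from other cells is argued against, since SLC12A1 in AC neutrophils was at least 29.5 times its level in T cells or mononuclear phagocytes of the same library. Reads shared with an overlapping called gene are argued against for MYEF2, which overlaps 0 genes called by edgeR, with or without the low-count filter, or by DESeq2. For 3 genes, AC066612.1 and AC066612.2 within SLC12A1 and AC023355.1 beside DUT, shared reads cannot be told apart from expression, because the strand use is not stated. The count of 5 genes at full depth was reached by 1 of 35 splits, the real one, and the highest of the others was 2. That share is the smallest that 35 splits allow, and the splits were chosen after the result was seen. The 5 genes are also neighbours, 3 of which may share reads. The splits thus argue against chance for this count without excluding it, and not for SLC12A1 and MYEF2 counted alone. The count fell to 1 with sums thinned to 918922 UMIs. Disease and donor variants remain open and untested, with 3 AC donors.

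The oxidative phosphorylation list was called lower in sAH than in AC blood neutrophils, with ribosomal proteins moving alike. A split of blood T cells into 4 libraries (2 AC, 2 sAH) and 3 called 444 genes, 436 of them higher, with 27 of 30 ribosomal and 23 of 30 oxidative phosphorylation genes among those, which points to a structure of the samples that crosses the diseases. That split parts the diseases almost evenly, so it does not go with them. In neutrophils it called 0 genes, so its use as a covariate there cannot decide whether such structure lies behind the list. With the covariate the neutrophil count stayed at 5 genes. The list stayed lower (median log2 fold change -1.03, against -0.85 without the covariate; camera adjusted p = 3.48e-08). With every sum thinned to 918922 UMIs the list stayed lower (camera adjusted p = 3.95e-06 with the preset correlation). Thinning a sum keeps the expected share of each gene, and depth per cell was not evened out, so this test cannot decide on depth. The list had an adjusted p = 0.551 with an estimated correlation, so the call itself is open. A difference between the diseases remains a hypothesis, untested beyond these 7 donors.

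CXCL8 and the stress lists were higher in liver than in blood of sAH donors. Free RNA is argued against for CXCL8, whose level in liver neutrophils was at least 199.7 times that in T cells of the same library. Macrophage RNA could bring at most 0.41% of neutrophil CXCL8, judged from C1QA, C1QB and C1QC. These genes are among the leading genes of phagocyte cluster 5 but not of cluster 12. RNA of phagocytes with little of them was thus not bounded. Digestion of the liver cannot be told apart from the tissue, since blood was not digested and the immediate-early list was higher in 4 of 4 cell classes. Residence in the diseased liver, which the design names, stays open and untested.

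For liver against blood, the 8 splits that part all 4 donor pairs are too few for a share under 0.05, with 1 of 8, the real one, at 730 genes in neutrophils, 2948 in mononuclear phagocytes, 2440 in T cells and 65 in NK cells, and the highest other at 0 in each class. The 27 splits left out put both tissues of a donor in one group. For the comparison by CXCL8 (97; highest other 54), 1 of 32 splits, the real one, reached the count, the smallest share that 32 splits allow. This argues against chance at the main setting without excluding it. Splits were not counted at the settings where the real count was lower. For the sAH and AC counts of blood mononuclear phagocytes (0; 1), T cells (0; 444) and NK cells (0; 42) the splits decide nothing, since 35 of 35 reach a count of 0 by construction.

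In 22 of 220 groups of 4 or 5 libraries, 1 library stood apart, its gap to the nearest other being most of the group's range, and chance gives this in about 1 in 20 groups, or 11 groups here. Of these, 7 were the liver library of sAH donor 5 and 5 the blood library of donor 4. The gap as a share of the range was 0.893 for total UMIs (blood of donor 5, high), and for B cell shares 0.874 (liver of donor 1) and 0.854 (blood of donor 4). In neutrophils it was high in the liver of donor 5 for DNAJB1 (0.909), CXCR2 (0.900), G0S2 (0.861), VEGFA (0.838), S100A8 (0.836) and CXCR4 (0.831), and in the liver of donor 3 for TNFAIP3 (0.846). It was low in the liver of donor 3 for NR4A3 (0.854) and in the liver of donor 2 for HLA-DRA (0.873). In blood neutrophils, donor 4 was high for CXCL8 (0.873, and 0.867 as scaled with AC blood), PHACTR1 (0.863) and MYEF2 (0.906), and donor 5 for P4HA1 (0.861). MYEF2 was at only 0.32 CPM in donor 4, against at most 0.03 CPM in the other sAH blood libraries, all very low levels. In T cells, DUSP1 was high in blood of donor 5 (0.959), GZMA high (0.965) and CCR7 low (0.883) in blood of donor 2, and HLA-DRB1 low in the liver of donor 2 (0.911). In NK cells, JUN was high in the liver of donor 5 (0.854).

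The share of neutrophils with CXCL8 was higher in sAH than in AC by 35.4 percentage points in liver and differed by -3.43 points in blood. That makes a difference of 38.8 points between the tissues, which was not tested. At Leiden resolution 2 the liver difference was 23.9 points, with 2 of 5 sAH livers below the AC liver. Of the 70 AC liver neutrophils at the main setting, 14 lay in cluster 3, which was 97.7% AC blood cells. The unnamed cluster 23 held 740 cells in sAH liver (3.48% of kept cells), 5 in the AC liver and 0 in blood. Its cells had a median of 1104 UMIs, and what they are was not tested.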

How the results depend on the processing

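The tests that count the cytotoxic cluster as T cells or leave out both libraries of sAH donor 3 were chosen only after the result was seen. For results that changed, the cause was not tested. A gene that left the tested genes under a setting has no value there.

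Without the low-count filter the counts of genes past the threshold were 9 (blood neutrophils), 1928 (liver against blood neutrophils), 71 (liver neutrophils, sAH against AC), 24 (comparison by CXCL8), 3 (blood NK cells) and 206 (liver against blood NK cells). DESeq2 gave 72 in blood neutrophils, 21 in blood mononuclear phagocytes, 1535 in liver against blood neutrophils, 4675 in mononuclear phagocytes, 4 in liver neutrophils, and 1 and 231 in NK cells. Donors as blocks gave 1950 genes in neutrophils and 145 in NK cells, and apart from the gene and list calls named in the report and with the NK cells, the block changed no other call of a named gene or list. Resolution 2 gave 241 in neutrophils and 2 by CXCL8, and no library block gave 0 by CXCL8 (edgeR; DESeq2 gave 83 with the block). For NK cells the fifth liver gave 105 and leaving out donor 3 gave 12. The cytotoxic cluster as T cells gave 1436. With an estimated correlation, 16 of the 108 calls among 222 list tests outside NK cells were kept.

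Leaving out each library in turn gave 2 to 7 genes in blood neutrophils. For liver against blood it gave 355 to 1074 in neutrophils, 1690 to 3825 in mononuclear phagocytes, 1780 to 2583 in T cells and 24 to 118 in NK cells. By CXCL8 it gave 52 to 139. The log2 fold change of CXCL8 ranged from -1.71 to -0.94 in blood and from 5.87 to 6.94 between tissues. The share of neutrophils with CXCL8 differed by 51.7 to 62.5 points between tissues and by -4.02 to -2.44 in blood. The neutrophil share differed by -36.9 to -25.4 points between tissues and by -15.8 to 5.57 in blood, where its sign turned without sAH donor 2 (5.57), AC donor 1 (5.39) or AC donor 3 (0.0095). In liver against blood neutrophils, CXCR2 ranged from -1.62 to 0.19 and S100A8 from -2.30 to 0.49, and both turned without the blood library of donor 5. Of 1974 alternative values for 123 named genes, 1890 kept side and direction, 70 lost the threshold, 12 gained it and 2 turned.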

Other observations

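The tests of NK cells were chosen only after the result was seen, since this class was added to the comparisons then.

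NK cells of sAH livers had higher early-response genes than blood NK cells of the same 4 donors. FOS, an immediate-early transcription factor, rose from 10.5 to 714 CPM (log2 fold change 6.07 ± 0.65, edgeR adjusted p = 0.00336), JUN by 5.84 (5.75 and not past the threshold without the low-count filter) and DUSP1, which switches off stress kinases, by 4.32. CD69, an activation and retention marker, rose by 3.26 ± 0.33, the cytokine gene TNF by 3.55, the glucose transporter SLC2A3 by 2.90 and NFKBIA by 2.40. Of 11326 genes, 63 rose and 2 fell (140 and 5 with donors as blocks), and 5.5% separated the tissues fully, where chance gives 2.86%. The count of 65 came to 28, 33 and 24 without the blood libraries of donors 2, 4 and 5, and to 118 without the liver library of donor 4.

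Immediate-early genes rose in 15 of 20 in NK cells (16 adjusted over the list alone; adjusted p = 6.91e-61, and 0.0157 with an estimated correlation). Heat shock genes rose in 6 of 18 (17 adjusted over the list alone; adjusted p = 8.48e-37 and 0.0324), NF-kB targets in 6 of 23 (13; 1.14e-24 and 0.0250), and tissue-residency genes in 4 of 13 (10; 8.42e-24 and 0.0166). The list of mature neutrophil receptors gained a call with donors as blocks (adjusted p = 0.0118, against 0.0546). Clusters 8 (64.6%) and 18 (35.4%) held NK cells of these 4 livers and cluster 8 held 99.6% of those of sAH blood.

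Blood NK cells of sAH and AC donors had 0 of 11594 genes past the threshold in edgeR, with 440 at an unadjusted p under 0.05 and 1 called by DESeq2. Mitochondrially encoded genes were called higher in sAH (median 0.75, adjusted p = 2.48e-08; adjusted p = 0.797 with an estimated correlation), as in the other 3 blood classes.

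The unnamed cytotoxic cluster 15, led by GZMH, GNLY and FGFBP2, held 1410 cells, or 0.918% of the kept cells of sAH liver, 0.0143% of the AC liver, 3.34% of sAH blood and 3.83% of AC blood. Some clusters were mostly 1 library. Of the neutrophil clusters, 17 came to 98.3% from 1 sAH liver, 16 to 98.2% from 1 sAH blood library and 3 to 86.7% from 1 AC blood library, and among T cell clusters 14 came to 96.0% from 1 liver, with DNAJB1 among its leading genes. Mononuclear phagocyte cluster 28 came to 92.9% from 1 sAH blood library.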
